A study of Drosophila melanogaster with 2 samples.

How the data were processed

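The data are ChIP-seq peak lists of fu2-GFP from whole Drosophila melanogaster embryos, 2 biological replicates of 1 group, with chromatin sheared by sonication to 200 to 800 bp per the labels. The 2 replicates carry separate biological replicate numbers in the labels. The authors deposited 8 lists in narrowPeak format, 4 on dm6 and 4 on dm3. Per the file manifests, the list of each replicate derives from its own alignment and the pooled list from both alignments, each with 1 further input that the manifests do not describe, and the IDR peaks derive from the replicate lists and the pooled list. The labels list a possible control experiment, and whether it is that input is not given in the sources used here, nor are the aligner, the peak caller and the IDR threshold. The values in the deposited lists are a signal value per region, the −log10 of a q-value, which is at its highest value in every IDR peak, and the offset of the summit from the region start, given by the authors in bp. Signal values of lists called separately are not on a shared scale and were compared only by rank or correlation, apart from the medians on the 2 builds. On dm6 the 3033 IDR peaks are the 3033 regions of the pooled list with the highest signal value (62.5 or more). Whether the lists of exactly 30000 regions were limited to that number is not given in the sources used here. The lists give no reads, so neither depth nor the precision it gives can be stated, and intervals cover counting over regions only. A control library and an unfused GFP sample were not analysed here, so no background measured in the same way stands beside the values.

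Coordinates were converted to 1-based positions. Genes, transcripts and exons came from Ensembl release 115 (BDGP 6.54) without transposable elements, sequence from the NCBI genome of the same assembly, Release 6, and every dm6 region lies on the main chromosome arms. On dm3, for which no annotation was used here, only counts, arms, signal values and the overlap of the replicates were taken, and no coordinates were converted. A summit within 500 bp of a transcript start was called a promoter summit, and the others were put in coding exon, UTR, other exon, intron or intergenic sequence in that order. The background for enrichment was the 26329 regions of the pooled list that overlap no IDR peak, since these could have passed the threshold. By its name the pooled list holds peaks and background, so these regions need not be bound sites. Enrichment was tested with the two-sided Fisher's exact test (sample odds ratio, Woolf 95% interval, 0.5 added to each cell where 1 is 0) and Benjamini-Hochberg adjustment within each family at 0.05. Stratified odds ratios are Mantel-Haenszel estimates. Overlap meant at least 1 bp, and the replicates were compared over their strongest 3033 regions with 1000 random placements.

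Before the data were examined, 38 gene lists (8 of them cell type markers), 22 consensus words, the tests and the rule for named genes were fixed. The rule takes prg, the 25 IDR peaks with the highest signal value, each named by the gene with the nearest transcript start, and up to 4 members of each gene list with the strongest promoter summit. Where fewer than 4 members are named in the text, the rest are left out for length. List members were compared with all other genes of their class, 13968 protein coding and 4309 non-coding genes, the latter including microRNA genes found by symbol. Words of 8 bases were found on 2L and 2R and the leading 20 tested on 3L, 3R and X. Alternatives tried were another overlap rule, promoter distances of 200 and 1000 bp, a window of 100 bp, the stronger part of the peaks alone, each replicate's strongest regions alone, random positions (10 per peak) as background, protein coding transcripts alone, genes with any listed region alone, the arms without Y, and strata of GC content or promoter location. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used. The code was tested on simulated data. Overlap calls matched a direct search in 4500 of 4500 cases, 60 of 60 planted gene list calls were recovered with 1 call among 620 unplanted ones, random draws of regions gave a promoter p below 0.05 in 2 of 100 draws and a motif call in 0 of 20, and the planted 8-mer came first with 0 calls among 13 unrelated words.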

Results

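Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where a GFP-tagged form of fu2 sits on the genome of Drosophila melanogaster embryos. fu2 is listed as a synonym of prg (FBgn0285971), a zinc finger gene on 2L, and the labels name prg as the gene targeted in the transgenic line. The embryos were whole, of mixed sex and 0 to 24 h old, and the immunoprecipitation used an antibody against GFP. There are 2 biological replicates of this 1 group, numbered 2 and 3 in the labels. The design therefore compares replicates with each other and IDR peaks with weaker listed regions or random positions, not conditions. The deposited dm6 lists hold 30000 regions for replicate 2, 30000 for replicate 3 and 30000 called on both together. The authors named this last, pooled list as peaks and background given to the irreproducible discovery rate (IDR) step. Of its regions, 3033 peaks passed the authors' IDR threshold. The lists give no read counts, so the depth is unknown. All positions are on dm6, and the signal value of a region is the authors' own and is used within its list, and between lists only by rank, by correlation and, for the 2 builds, by its median.

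The comparison of the replicates asked how far they ranked the same regions first. Of the 3033 strongest regions of replicate 2, 77.5% overlapped one of the 3033 strongest of replicate 3, and 77.7% did in the other direction. The same 5 peaks led both lists in the same order: those nearest to CG14100, cbt, Ugalt, mRpL41 and lncRNA:CR44619. Each of the 25 strongest IDR peaks ranked 26 or better in replicate 2 and 29 or better in replicate 3. Random placement of the replicate 2 regions on their arms gave 1.65% overlap on average and at most 2.34% (one-sided permutation test, p = 0.001, the smallest that 1000 placements can give). Random regions of the replicate 2 list, a chance value added after the data were seen, gave 11.7% on average and at most 13.4%. Across 9963 regions with summits within 100 bp of each other, the signal values of the replicates had a Spearman correlation of 0.724 and a Pearson correlation of 0.828 on the log2 scale, described across regions, which are not independent replicates. Of the 3033 IDR peaks, 3029 (99.9%, lower end of the exact 95% interval 99.7%) overlapped a listed region in both replicates, and 2350 (77.5%) overlapped the strongest regions of both. Since the IDR peaks were selected from these lists, this describes the selection and is no separate measure of how alike the replicates were.

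fu2-GFP peaks lay mainly at promoters and hardly ever in coding sequence away from transcript starts. Of the 3033 IDR peaks, 1933 (63.7%) had their summit within 500 bp of an annotated transcript start, against 29.5% of the 26329 regions of the pooled list that overlap no IDR peak. Introns held 26.2% of the peaks (794) and intergenic sequence 8.28% (251). Coding exons held 6 peaks (0.198%) against 15.6% of the regions under the threshold, and these 6 summits lay in otp, klar, CG10357, Pde1c, CG33181 and Obsc, named here because the count is so low. The replicates gave the same picture when taken alone, with 63.4% ± 0.396 (SD, n = 2) of their strongest regions at promoters and 0.346% ± 0.0233 (SD, n = 2) in coding exons. By two-sided Fisher's exact test with Benjamini-Hochberg adjustment over 6 classes, the odds ratio was 4.20 for promoters (95% interval 3.88 to 4.54, adjusted p = 6.69e-293) and 0.0107 for coding exons (0.00481 to 0.0239, adjusted p = 2.10e-197). Introns (0.636), intergenic sequence (0.516) and UTRs (0.300) were also less frequent among peaks, and other exons did not pass (0.650, adjusted exact p = 0.0713). Regions are the units of these tests, so the p-values measure counting over regions and not the spread between replicates. The promoter odds ratio moved by over 1.5 times with the background, to 11.1 against random positions and to 1.67 against the 3033 strongest regions under the threshold, a background added after the data were seen. Against the same strongest regions the coding exon odds ratio was 0.103 (0.0446 to 0.240). Summits in coding sequence or UTRs within 500 bp of a start were counted as promoter summits. With a promoter distance of 200 bp, coding exons held 12 peaks (0.396%) against 19.75% of the regions under the threshold (odds ratio 0.0161).

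**Figure D1:**
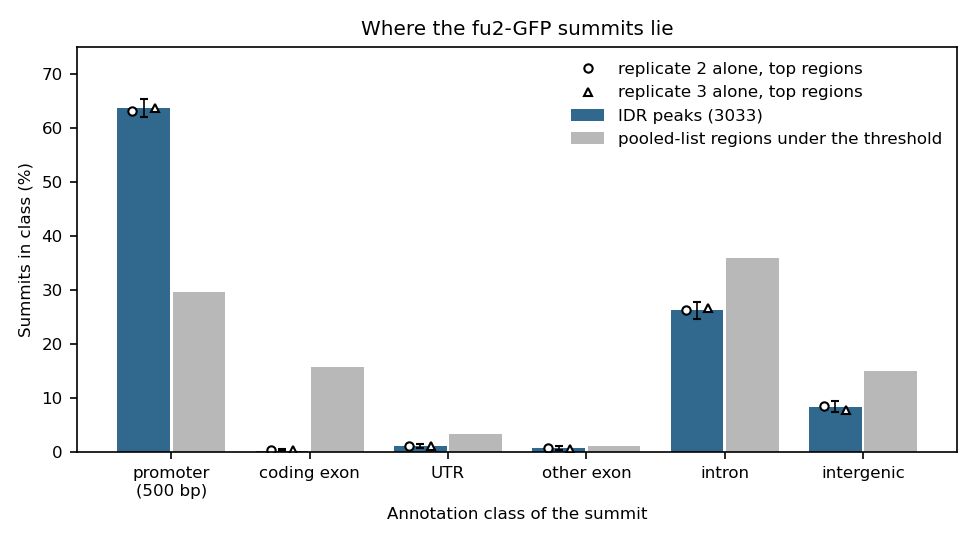
Percent of summits (y axis) in each annotation class (x axis) for the 3033 IDR peaks (blue bars, with exact 95% binomial intervals) and for the 26329 pooled-list regions under the threshold (grey bars); open circles and triangles are the strongest regions of replicate 2 and of replicate 3 alone. Promoters hold 63.7% of the peaks and 29.5% of the regions under the threshold, and coding exons 0.198% and 15.6%.

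The strongest peaks stood at genes of varied function. The first was 97 bp upstream of CG14100 (FBgn0036889) at 3L, 19590410 to 19590817, with a signal value of 1729, rank 1 in both replicates. The next, at 2L, 480883 to 481301 (1584), was nearest to cbt, which encodes a zinc finger transcription factor, but its summit was 1397 bp from that start and in an intron of ush, the gene of a GATA cofactor. Peaks followed at Ugalt (X, 2703688 to 2704084, signal 1342), the gene of a nucleotide sugar transporter, and at mRpL41 (2R, 15217578 to 15217998, signal 1157), the gene of a mitochondrial ribosomal protein. The peak at lncRNA:CR44619 on X (1059) was 449 bp upstream of its start and inside lncRNA:Vinr. The peaks at CG11050 (1030), at the kinase gene Lk6 (1019), at CG9663 (795.9) and at CG32772 (750.5) lay in introns of those genes, 1028, 966, 962 and 1257 bp from the nearest start. Promoter peaks stood at Shc (935.1), PNPase (913.7), Chro (904.7), px (883.8), Tcs5 (851.1), ph-p (832.4), Pal1 (830.1), CenG1A (828.1), Art3 (815.2), CG1888 (809.8), CG31145 (790.9), asRNA:CR45928 (765.4), the transcription factor gene Atf3 (751.8), larp (741.6) and CG8320 (698.9). Chro encodes the chromodomain protein Chromator, and ph-p the Polycomb group protein Polyhomeotic proximal. Several of these starts are shared: mRpS23 starts beside CenG1A, mRpS10 beside Art3, Ssl1 beside Chro and eIF6 beside asRNA:CR45928, each within 500 bp of the summit. The peak nearest to CG13323 (2R, 13035162 to 13035524, signal 751.8) was intergenic, 11916 bp away. Of these 25 peaks 19 were at promoters, 5 in introns and 1 between genes. Over all promoter peaks, 864 of 1933 (44.7%) were within 500 bp of the starts of 2 or more genes, so that the gene a peak belongs to is often open.

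Cytosolic ribosomal protein genes carried peaks far more often than other genes. A peak summit stood within 500 bp of a transcript start at 62 of 92 of them (67.4%, exact 95% interval 56.8% to 76.8%), against 17.2% of the other protein coding genes, and each replicate alone gave 68.5% (SD 0, n = 2). RpS27 (signal 492.3, rank 52), RpL7 (437.8, rank 65), RpL23A (321.1, rank 131) and RpL34b (310.5, rank 142) had the strongest. Mitochondrial ribosomal protein genes had a peak at 25 of 73 (34.2%), among them mRpL41 (1157), mRpS23 (828.1), mRpS10 (815.2) and mRpL23 (533.9). These were 2 of the 3 lists of 38 that passed the two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 38 lists. The odds ratios were 9.97 for cytosolic ribosomal proteins (95% interval 6.43 to 15.5, adjusted exact p = 1.35e-24) and 2.47 for mitochondrial ribosomal proteins (1.52 to 4.01, adjusted p = 0.00662). When only genes with any listed region were compared, the odds ratio for cytosolic ribosomal proteins was 5.76 (3.59 to 9.26) and the call for mitochondrial ribosomal proteins was lost (odds ratio 1.34, adjusted exact p = 0.569). Of the 38 lists 12 had an unadjusted p below 0.05. The remaining list to pass was that of 111 replication-dependent histone genes, none with a peak. No region of any strength was listed over their cluster, so their count was set beforehand and is not read as a result.

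Several lists of chromatin, cell cycle and gene expression machinery had peaks at more members than the 17.5% of all protein coding genes, without passing the adjusted test. The Polycomb group had 8 of 18 (odds ratio 3.78, adjusted exact p = 0.0598), with ph-p (832.4), Sfmbt (197.6), Su(z)12 (171.3) and E(z) (107.4) in front, but an odds ratio of 2.40 with replicate 3 alone and 1.75 among genes with a listed region. The trithorax group had 8 of 19 (adjusted exact p = 0.0598), led by Trl (256.5), Bap60 (198.3) and brm (183.4). Insulator and architectural protein genes had 8 of 20 (adjusted exact p = 0.0631), with Chro (904.7), Trl, Dref (186.1) and Cp190 (182.1). Heterochromatin and dosage compensation genes had 7 of 17 (adjusted exact p = 0.0720), with JIL-1 (101.1) and HP4 (95.31), but 1 of 17 among the stronger part of the peaks (odds ratio 0.584) and odds ratios of 2.00 and 4.25 with replicate 3 and replicate 2 alone. Mitosis and cell cycle genes had 11 of 29 (adjusted exact p = 0.0598), with Dp (309.4), aurA (148.5), BubR1 (125.8) and Bub3 (124.5), and DNA replication genes 10 of 29 (adjusted p = 0.0860), with dup (216.3) and dpa (210.0). Translation initiation factor genes had 15 of 44 (34.1%, adjusted exact p = 0.0598), with eIF6 (765.4) and eIF3c (250.8) in front and 11 members in replicate 2 alone, and RNA polymerase II and general transcription factor genes 12 of 35 (34.3%, adjusted p = 0.0631), with Polr2F (294.5) and Polr2H (291.3). The piRNA pathway had 2 of 22 (9.09%; piwi, 82.09, and cuff, 68.96). Other counts were ZAD zinc finger genes (7 of 22 and 5 in replicate 3 alone, Sry-delta 166.4), Mediator subunits (9 of 29, MED30 361.5), heat shock and chaperone genes (7 of 24, Hsp83 187.7), tRNA synthetases (9 of 32, SerRS 235.6) and spliceosome proteins (6 of 25, SF2 151.2). Oxidative phosphorylation genes (18 of 87, 20.7%) and proteasome genes (10 of 48, 20.8%) were near the share of all other genes, with ND-MWFE (303.3) and Rpn5 (248.5) strongest.

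Most lists of developmental and cell type genes had a peak at few members, though none passed on its own (lowest adjusted exact p = 0.157). Ecdysone response (17.6%), fat body and germ line (16.7% each) and muscle genes (15.4%) were near the 17.5% of all protein coding genes, but in replicate 2 alone fat body genes had 6 of 18 and germ line genes 3 of 12. Of the dorsoventral patterning and mesoderm list 0 of 18 had a peak, of the gap and pair-rule list 1 of 20 (cnc, 96.84), of the Hox and homeotic list 1 of 15 (bcd, 84.84), of the early zygotic list 1 of 21 (Sxl, 149.8), of the proneural and Enhancer of split list 1 of 21 (E(spl)m3-HLH, 108.9), of the signalling ligand list 2 of 29 (spi, 318.1, and Wnt6, 67.24, but 4 in replicate 2 alone and 1 in replicate 3 alone) and of the ecdysone response list 3 of 17 (Eip75B, 221.6, usp and Hr39). Among cell type markers, muscle genes had 4 of 26 (Msp300 at 640.7, sls at 196.8, Mef2 and how), fat body genes 3 of 18 (Lpin, bmm and Adh), germ line genes 2 of 12 (bgcn, 159.2, and tud), neuron genes 1 of 23 (elav, 299.1, and 2 in replicate 3 alone), glia genes 1 of 19 (moody, 346.8), gut genes 1 of 21 (fkh, 128.7), trachea and epidermis genes 1 of 19 (shn, 82.15) and hemocyte genes 0 of 18. Among non-coding genes, where 3.69% of all had a peak, snRNA genes had 4 of 32 (adjusted exact p = 0.0909, 2 in replicate 2 alone and 3 in replicate 3 alone), with snRNA:U6:96Ab and snRNA:U6:96Ac counted from the same peak, tRNA genes 11 of 290, snoRNA genes 12 of 269 and microRNA genes 6 of 260.

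**Figure D2:**
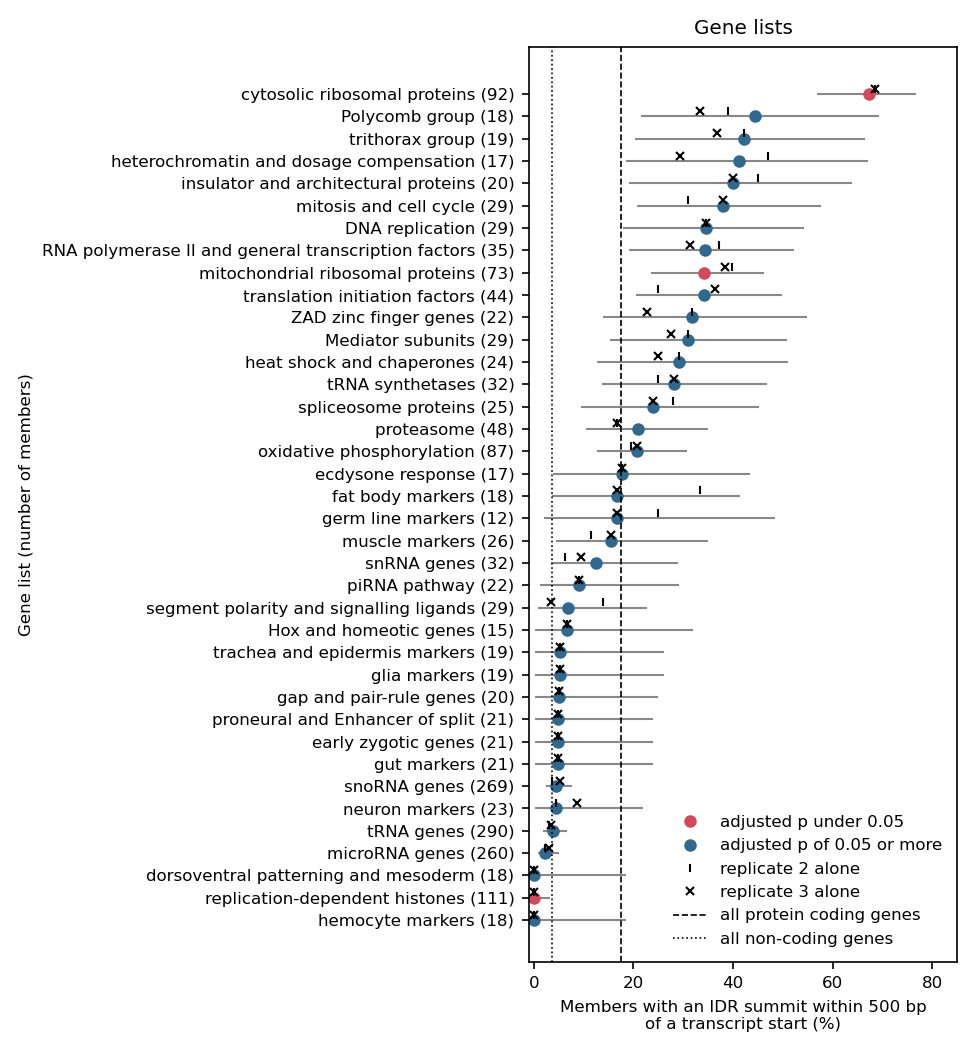
Percent of list members with an IDR summit within 500 bp of a transcript start (x axis) for the 38 gene lists (y axis, number of members in brackets); horizontal lines are exact 95% binomial intervals, and bars and crosses are replicate 2 and replicate 3 alone. Cytosolic ribosomal protein genes stand apart at 67.4%, while most developmental and cell type lists lie left of the dashed line at 17.5%, the share of all protein coding genes.

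DNA under the summits was A/T-rich and held words known from housekeeping promoters. The median GC content within 50 bp of the summit was 36.6% in peaks, 45.5% in regions under the threshold and 42.6% at random positions. The element TATCGATA, bound by DREF and BEAF-32, was present in 3.00% of peaks against 0.931% (odds ratio 3.29, 95% interval 2.58 to 4.20, adjusted exact p = 7.03e-17), and core promoter motif 7 in 4.58% against 1.93% (2.44, adjusted p = 4.75e-16). The M1BP motif (2.09), core promoter motif 6 (1.86), the TATA box (1.78), GATA sites (1.41) and Hox-type sites (1.31) were also more frequent. The GAGA repeat (0.648), the Pho core (0.660), the Runt site (0.630), the downstream promoter element (0.629) and the initiator (0.848) were less frequent. These are 12 of 22 consensus words tested by two-sided Fisher's exact test, adjusted over the 22. Stratified by GC content, the DRE (2.73), motif 7 (2.49) and the M1BP motif (2.26) stayed more frequent. The Pho core (0.764), the initiator (0.805) and the Runt site (0.700) stayed less frequent. The CTCF core (1.76) and the E-box CAGCTG (1.55) passed in these strata. They also passed against random positions, but not in the main test (1.11 and 1.00) or in any other alternative. Stratified by promoter location, the DRE fell to 1.72, motif 7 to 1.72 and the M1BP motif to 1.01, which lost its call. The M1BP motif also lost its call among the stronger part of the peaks (0.852). In the GC strata the TATA box (0.989), GATA sites (0.977), motif 6 (1.17), the downstream promoter element (1.01) and the GAGA repeat (0.912) lost the call. Hox-type sites passed there in the other direction, as less frequent among peaks (0.887, 95% interval 0.809 to 0.973). Against the 3033 strongest regions under the threshold, a background also added after the data were seen, none of the 22 passed. There the DRE had an odds ratio of 1.09 (3.00% against 2.77%) and motif 7 of 1.22. Hox-type sites came closest to passing (adjusted exact p = 0.0714).

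Among all 8-mers, the word with the lowest p on 2L and 2R was CAACACTG (reverse complement CAGTGTTG). On the arms held out for testing, 3L, 3R and X, it was within 50 bp of 3.34% of 1886 peak summits and of 0.558% of 16142 background summits (odds ratio 6.16, 95% interval 4.45 to 8.54, adjusted exact p = 6.96e-22). Related words passed as well: CAGCCCTG (odds ratio 5.43), CAACCCTG (4.61), AGTGTTGG (4.98), AACACTGC (2.87) and CAGCACTG (2.49). Of these, CAGCCCTG and CAGCACTG match the word tested as core promoter motif 7 (CAKCNCTA, K is G or T, N is any base) in all but the last base. Whether this group of words is separate from motif 7 was not tested. A further group resembled the DRE, with AACTATCG (5.86), ACTATCGA (4.09), ATCGATAG and TATCGATA itself (3.26). Words within this group overlap when shifted by a base, as AACACTGC and AGTGTTGG do with CAACACTG. Overlapping words can count the same sites, so their results are not independent of each other. The other 10 were A/T-rich, such as TTTAAAAA (2.37). All 20 words passed on the held-out arms by two-sided Fisher's exact test adjusted over the 20, and 12 did when stratified by GC content, an alternative added after the data were seen. CAACACTG then had an odds ratio of 6.65, and TTTAAAAA 1.25. The 8-mers were not compared with the strongest regions under the threshold, against which no consensus word passed. TATCGATA is the same word as the DRE, which had an odds ratio of 1.09 there over all arms. Whether the other 8-mers separate peaks from those regions is therefore open. When the words were searched again in the strongest regions of replicate 2 alone, ATTTTTAA had the lowest p on 2L and 2R and CAACACTG came next, with an odds ratio of 5.61 on the held-out arms against 2.25 for ATTTTTAA.

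**Figure D3:**
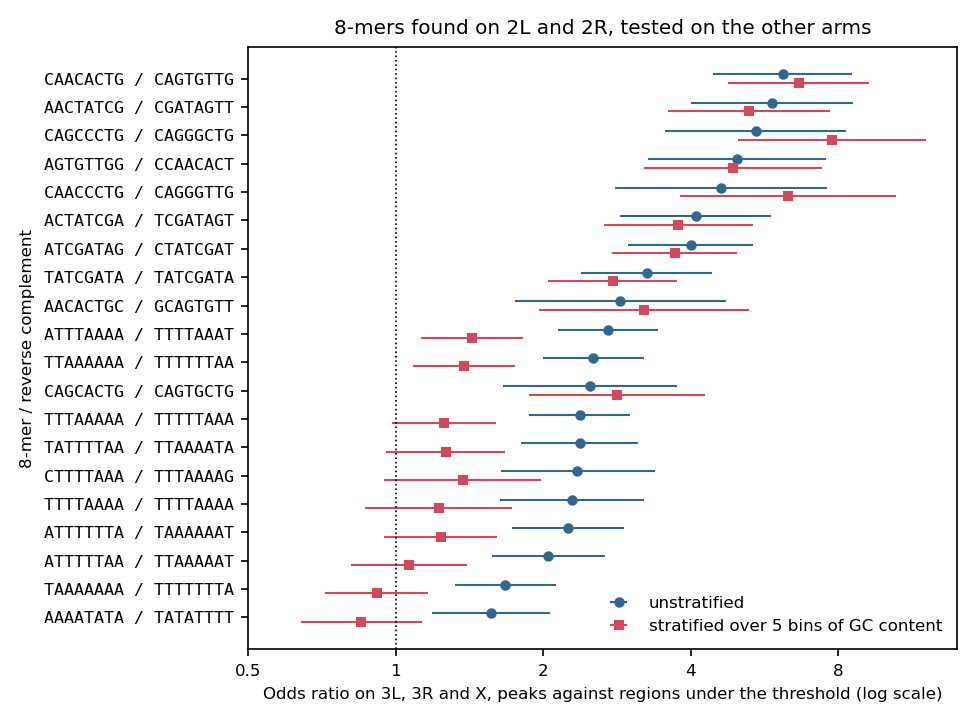
Odds ratio (x axis, log scale) with 95% interval of the 20 8-mers (y axis) found on 2L and 2R, measured on 3L, 3R and X in IDR peaks against regions under the threshold; blue circles are unstratified and red squares are stratified over 5 bins of GC content. CAACACTG stands at 6.16 and 6.65, while the A/T-rich words move towards 1.

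Peaks were spread over the large chromosome arms at 22.1 to 24.3 per Mb. Arm 2L had 571 peaks (24.3 per Mb, exact 95% interval 22.5 to 26.1) where its length would give 518.5 (two-sided exact binomial test, adjusted p = 0.0377 over 7 arms). The small chromosome 4 had 17 peaks (12.6 per Mb) where 29.7 were expected (adjusted exact p = 0.0377). X had 553 peaks (23.5 per Mb, adjusted exact p = 0.186). The lists hold no region of any strength on Y, so its 0 peaks carry no information, while counting it changes the expected counts of the other arms and their adjustment. With Y left out, an alternative added after the data were seen, no arm passed by length (2L, exact adjusted p = 0.209, chromosome 4, 0.0637). Against the regions under the threshold X had an odds ratio of 1.14 (adjusted exact p = 0.0546 over 7 arms and 0.0468 without Y), and with replicate 2 alone it passed (1.21, adjusted p = 0.00120).

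Peaks at promoters were slightly stronger than the rest. The median signal value was 99.6 at 1933 promoter peaks and 93.6 at the 1100 others, a difference of 0.09 on the log2 scale (95% bootstrap interval 0.03 to 0.15, two-sided permutation test with 100000 resamples, p = 0.00439). With promoters defined by 200 bp the difference was 0.04 and did not pass (permutation p = 0.247), and with replicate 2 alone it was 0.14 and with replicate 3 alone 0.07.

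At prg, the gene of the tagged protein (2L, 8464488 to 8466694, plus strand), 2 IDR peaks lay just upstream. The nearer (8464153 to 8464556, signal 158.6, rank 631 of 3033) had its summit 133 bp upstream of the gene start and also within 500 bp of the start of Agpat2, which is transcribed the other way. The farther (8463138 to 8463541, signal 134.1, rank 863) lay in an intron of Agpat2. Within prg, a region under the threshold lay in coding sequence (8464964 to 8465367, signal 29.4, rank 9145), and another stood downstream at the start of dachs (27.9, rank 10029). Replicate 2 ranked the IDR peaks 632 and 596, and replicate 3 ranked them 671 and 1010. Copies of the locus added by the transgene were not told apart from the native gene here.

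**Figure D4:**
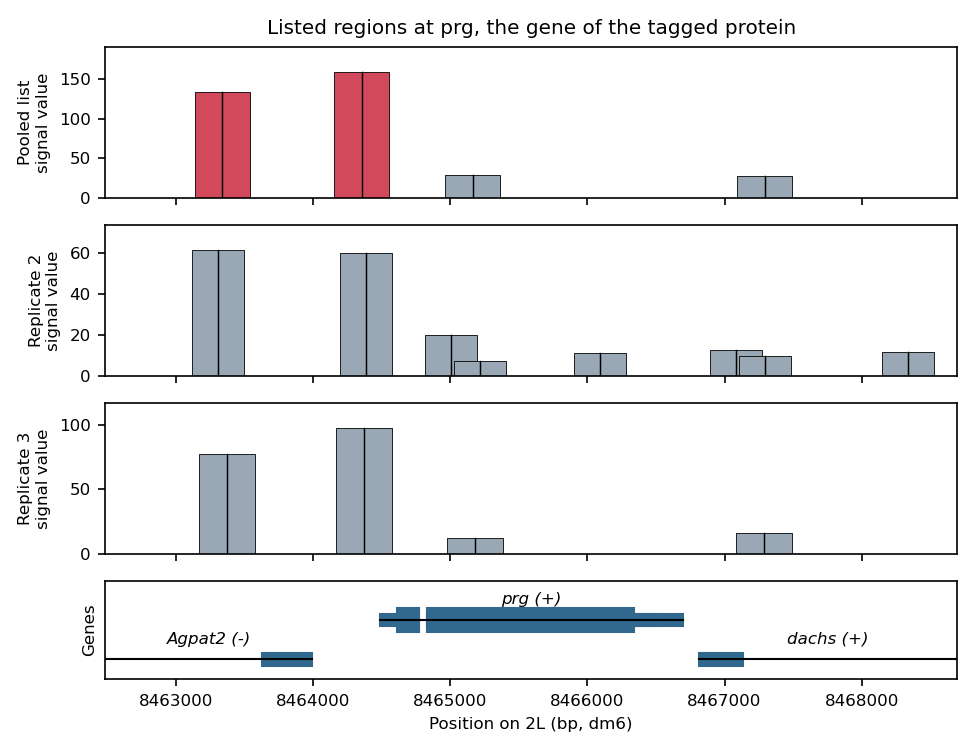
Signal value (y axis, authors' own, separate scale per list) of every listed region across 2L around prg (x axis, dm6), in the pooled list, in replicate 2 and in replicate 3, with summits as black lines. In the pooled list IDR peaks are red and other regions grey. All regions of the replicates are grey, including those at the IDR peaks. Gene models are below, tall boxes being coding sequence. The IDR peaks, at 158.6 and 134.1, stand upstream of prg, and regions within it reach 29.4.

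The same experiment was also processed by the authors on the older build dm3, where 2935 peaks passed the IDR threshold. Their median signal value was 98.8, against 97.2 on dm6, a ratio of 1.02 (bootstrap SD 0.0156). The arms held similar shares on dm3 and dm6, such as 19.1% and 18.8% on 2L, 18.1% and 18.2% on X and 0.579% and 0.561% on chromosome 4. On dm3 1 peak lay outside the main arms.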

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

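The backgrounds made of the strongest regions under the threshold, the chance value drawn from the replicate 2 list, the arms without Y, the classes of lists among genes with a listed region and the GC strata for 8-mers were chosen after seeing the data; the other alternatives were planned. The promoter odds ratio stayed above 1 and past the threshold in every alternative (1.67 to 11.1), and 5 feature classes passed under each alternative. Replicate overlap ran from 50.7% for all regions to 79.6% and passed in each. The correlation of signal values was 0.759 for summits within 50 bp and 0.651 within 250 bp. IDR peaks with a region in both replicates fell to 87.6% for mutual overlap of a large part of each region and to 95.2% for summits within 100 bp. The promoter difference in signal was 0.0370 at 200 bp, no longer past the threshold. With the stronger part of the peaks alone, 13 8-mers passed, from fewer peaks, and 1 arm, which was Y, so that 2L and chromosome 4 lost their calls (adjusted p 0.0846 each). With Y left out 0 arms passed by length. GC strata left 12 8-mers. Gene lists past the threshold numbered 6 at 200 bp, 10 at 1000 bp (among them snoRNA genes, Polycomb and trithorax groups), 1 among genes with a listed region, where histone genes drop out, and 4 to 6 with a replicate left out. The histone list is among those counted, except where it drops out. No consensus word passed (0) against the strongest regions under the threshold; the cause was not tested.

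Leaving out a replicate in turn gave a promoter difference in signal of 0.0675 to 0.138, 5 feature classes, 3 arms (Y among them), 11 words of 22 and 20 8-mers. The downstream promoter element lost its call without replicate 2 (0.762), the GAGA repeat (0.859) and the initiator (0.931) without replicate 3. The AP-1 site gained a call without replicate 3 (1.53). With replicate 3 left out the 8-mer with the lowest p was ATTTTTAA (2.25), CAACACTG came next (5.61), and 12 of the 20 words were shared. The 8-mers were searched anew each time, and 13 words were shared with replicate 2 left out. Odds ratios of single gene lists and consensus words turned to the other side of 1 in 45 recomputed values. Most had not passed to begin with, but the M1BP motif, motif 6, the GAGA repeat, the TATA box, GATA and Hox-type sites and the downstream promoter element had. At 200 bp these were tRNA genes (0.429), snoRNA genes (0.969) and germ line markers (1.34); at 1000 bp tRNA genes (0.872) and fat body markers (1.15). With the stronger part of the peaks they were tRNA genes (0.423), snRNA genes (0.640), heterochromatin and ecdysone lists (0.584 each), fat body markers (1.87), the M1BP motif (0.852), the CTCF core (0.960), the E-box CAGCTG (0.856) and the TCF site (1.06). Among genes with a listed region they were oxidative phosphorylation (0.836), proteasome (0.950), spliceosome (0.771), tRNA genes (0.752), ecdysone response (0.728) and fat body markers (1.09). With a replicate left out they ran over proteasome 0.953 to 0.960, tRNA genes 0.838 to 0.890, fat body markers 0.960 to 2.39, germ line markers 0.960 to 1.59, the Su(Hw) core 0.763 to 1.61, CAGCTG 0.924 to 1.01 and the TCF site 0.870 to 1.06. Against random positions they were the GAGA repeat (1.05) and the Zelda site (1.13), and in windows of 100 bp the GAGA repeat (1.00), the E-box CACGTG (1.05) and the TCF site (1.06). Stratified by promoter location, CAGCTG had 0.883, and the M1BP motif (1.01) lost its call. Stratified by GC content, the Zelda site (1.33), CACGTG (1.14), CATATG (0.992) and GATA (0.977) turned. So did the TATA box (0.989), the downstream promoter element (1.01) and the Hox-type site (0.887), the last passing below 1. The peaks are A/T-rich, and 5 bins of GC content need not remove that difference in full. Against the strongest regions under the threshold they were the M1BP motif (0.747), motif 6 (0.992) and the Zelda site (1.29). The cause of the turns was not tested. The 8-mers are not counted among the 45. Stratified by GC content, TAAAAAAA (1.675 to 0.914) and AAAATATA (1.565 to 0.850), which had passed, turned as well.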

Other observations

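All comparisons in these first paragraphs were chosen after the data were seen. Joined by class, of 382 housekeeping genes other than ribosomal proteins and histones, 107 (28.0%) had a peak (odds ratio 1.87, 95% interval 1.49 to 2.35, adjusted exact p = 7.27e-07), and of 111 chromatin genes 37 did (33.3%, odds ratio 2.38, adjusted p = 9.19e-05). Of 130 developmental genes 9 had a peak (6.92%, odds ratio 0.348, 0.177 to 0.687, adjusted exact p = 0.00103), and of 151 cell type marker genes 13 (8.61%, odds ratio 0.441, adjusted p = 0.00294). These are two-sided Fisher's exact tests against all other protein coding genes, adjusted over 6 classes. Among genes with any listed region, these housekeeping genes (35.3% against 31.2%, 95% interval of the odds ratio 0.945 to 1.53) and chromatin genes (odds ratio 1.31, 0.868 to 1.97) no longer passed, while developmental (0.331, 0.164 to 0.668) and cell type marker genes (0.421, 0.232 to 0.764) still did. Promoter summits of fu2-GFP peaks lay upstream of the nearest transcript start in 1558 of 1933 cases (80.6%), at a median of -71 bp, while those of regions under the threshold did in 45.2% of 7771 cases, at a median of 20 bp (odds ratio 5.03, 95% interval 4.46 to 5.68). A summit between starts that point away from each other counts as upstream whichever is nearer. Such promoters were not split off, and 44.7% of the promoter peaks were near the starts of 2 or more genes.

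On 3L, 3R and X, where CAACACTG was not chosen, it stood within 50 bp of the summit in 59 of 1165 promoter peaks (5.06%). Promoter regions under the threshold held it in 50 of 4641 cases (odds ratio 4.90, 95% interval 3.34 to 7.18). Other peaks held it in 4 of 721 cases (odds ratio 1.60, 0.570 to 4.48). The degenerate form CARCMCTG (R is A or G, M is A or C), which covers CAACACTG, CAACCCTG, CAGCCCTG and CAGCACTG, was in 11.2% of promoter peaks against 3.43% on these arms (3.54, 2.78 to 4.51), and in 1.66% of other peaks against 1.14% (1.47, 0.809 to 2.67). CARCMCTG was put together after the data were seen, so these arms are not held out for it. The odds ratios at promoters and elsewhere were not tested against each other. For CARCMCTG no tie to strength was seen: 6.98% of the strongest 759 peaks and 8.97% of the weakest 758 held it (odds ratio 0.762, 0.524 to 1.11, exact p = 0.157). None of the 25 strongest peaks held CARCMCTG or the DRE (0 of 25 each). Over all IDR peaks the shares were 8.47% and 3.00%, so few would fall among 25, and 0 is not read as a difference. The 25 strongest peaks had a median GC content of 31.7%, against 33.7% in the strongest 758 and 38.6% in the weakest 758. Of 10 6-mers that best separated the strongest from the weakest 758 on 2L and 2R, CTTAAA (odds ratio 1.91, adjusted exact p = 0.00902) and ATTTAA (27.0% against 19.6%, odds ratio 1.51, adjusted p = 0.0440) passed on 3L, 3R and X. Both words are A/T-rich, as are the strongest peaks, and the 6-mers were not stratified by GC content. Of 66 peaks at ribosomal protein genes, 11 (16.7%) held the DRE, against 4.33% of 1802 peaks at other protein coding genes with no ribosomal protein start within 500 bp.

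For the patterns that follow, the tests of ribosomal protein genes against oxidative phosphorylation and proteasome genes, and of coding exons against the strongest regions under the threshold, were chosen after their results were seen. The high share of cytosolic ribosomal protein genes with a peak (67.4%, exact 95% interval 56.8% to 76.8%) could come from strong transcription, which can raise signal in any immunoprecipitation. Oxidative phosphorylation and proteasome genes had a peak in 20.7% of 135 cases (14.3% to 28.6%), but they were picked after their shares were seen and no table holds their transcription, so this explanation stays open. Crowded transcript starts could also put a neighbour's peak within reach, but stratified by the number of other genes starting within 500 bp the odds ratio was still 8.29 (5.20 to 13.2). Open chromatin at these promoters and signal of the antibody without fu2-GFP stay open, since no accessibility data or control list was analysed here, and no biological explanation was tested.

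The scarcity of peaks in coding exons (6 of 3033 against 15.6%) could follow from base composition, since coding sequence is GC-rich and peaks are not. Stratified over 5 bins of GC content the odds ratio was 0.0234 (0.0101 to 0.0544), which argues against base composition as the whole cause. The contrast could also be set by unspecific regions at the weak end of the list, which the authors named as peaks and background. The weakest 3033 regions had 19.5% of summits in coding exons (18.1% to 21.0%), the strongest 3033 under the threshold 1.88% (1.43% to 2.43%) and random positions 14.2%. Such a fall with strength would also be seen without unspecific regions, so how much they add stays open. Against the strongest 3033 under the threshold, which leaves the weak end out, the odds ratio was still 0.103 (0.0446 to 0.240). The weakest regions alone therefore do not make the contrast. Regions just under the threshold can be unspecific too, so this comparison cannot decide on unspecific regions, and no biological explanation was tested.

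The absence of peaks at replication-dependent histone genes may reflect reads shared between near-identical gene copies. The cluster of 111 genes on 2L (21416953 to 21541681) held 0 regions of any strength in the pooled list, where the density of the arm would give 29.6, so for reads shared between near-identical gene copies, as set out before the count, the density of listed regions in the histone cluster over that of the arm was 0. Neither replicate listed a region there (30.3 and 29.3 expected). The lists therefore say nothing on fu2-GFP at these genes, and no biological explanation was tested.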
